A study of Homo sapiens with 48 samples.

How the data were processed

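RNA from ARPE-19 cells was measured on 48 spotted arrays, each with day 0 RNA in 1 channel and RNA of a starved day in the other. Per the labels, the channels were Alexa 555 and Alexa 647, total RNA was extracted with Trizol and the cDNA was labelled through amino-allyl groups. The groups are the starved days 1, 3, 5 and 7, taken from the labels, and the replicate is the time course number.

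Per the file headers, the deposited scanner files were made with BlueFuse for Microarrays version 3.6. They hold an intensity for each channel of each of 30000 spots in 48 print blocks, which the authors deposited without foreground and background columns, so what was done about background is not given in the sources used here. They also hold, per the file headers, the fraction named P ON for each channel, used here as the detection measure. The authors' exclusion marks, set by hand or automatically, removed a median of 66.7% of spots (21.8 to 87.1% over arrays). The highest confidence value among automatically excluded spots of nonzero quality was 0.2 on 15 of 16 arrays of time course 1 and 0.3 on the other and in time courses 2 and 3. The authors' value table of 13167 clones holds deposited log2 ratios of starved over day 0, with column medians between -0.10 and 0.15. Its scale and direction were settled by setting each column against the scanner values: the correlation was 0.970 or more in time courses 2 and 3, with slopes of 0.98 to 1.00, and 1.00 with a slope of 1.00 on the 1 array of time course 1 with automatic marks up to 0.3. On the 15 arrays with marks up to 0.2 the correlation was 0.751 to 0.903 and the slope 0.59 to 0.80, and how the authors normalized these 15 is unknown. The 422 clone identifiers with no row in that table were not analysed here.

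Intensities were used as given. Spots with an exclusion mark and control spots had weight 0 in a loess fit of the log2 ratio on mean log2 intensity within each array (span 0.3, 4 iterations) and were left out of the averages, and there was no scaling between arrays. Spots of 1 clone, usually 2, were averaged. Within each day and time course the arrays of each dye orientation were averaged and the difference of the orientations was divided by 2, which cancels a dye effect that is equal in both. The detection rule fixed beforehand compared foreground with background, which these files do not hold, so P ON was used in its place: a clone counted as detected on an array where a spot had P ON of at least 0.5 in a channel, and a clone was to be tested when detected in at least 1 channel on at least 24 of 48 arrays (12377 clones). A value in all 12 day and time course combinations was required as well, which left 1387 clones, and the detection rule removed none of these. This requirement was set after the files were seen and before any test. The restriction to clones in the authors' value table was put in after first counts over all 1429 complete clones had been seen, and those counts are given among the alternatives.

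Tests used limma 3.58.1 in R 4.3.3: lmFit and eBayes on the 12 values with a mean for each day and 8 residual degrees of freedom, each day against 0, 4 differences between days and an F test of the 3 independent differences, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Changes of at least 2-fold were counted as well. Figures were drawn with matplotlib 3.10.9, and statmod 1.5.0 served the correlation within blocks. Because each array carries day 0 RNA, the test leaves out the spread of day 0 itself where 1 day 0 RNA served several arrays. The functions were tested on simulated data in 10 runs, each with 200 changed clones among 1387, drawn with the residual spread and dye parts of the real values. For day 7 against day 0, 68.8% of clones changed 1.5-fold, 94.5% of those changed 2-fold and 99.7% of those changed 3-fold were recovered. For day 7 minus day 1 the shares were 34.8, 79.7 and 96.7%. In the mean 8.2 unchanged clones were called for day 7 against day 0 and 5.1 for day 7 minus day 1. The simulated dye parts cancelled exactly, and the noise was independent between clones. With 200 changed clones the adjusted threshold is also easier to pass than with few, so recovery in the real values may be lower.

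The time course numbers come from the labels and mark a shared course. Deviations from the day means correlated at 0.18 in the mean between days of 1 time course (-0.26 to 0.47 over 18 pairs) and at -0.09 between days of different time courses. The deviations of a day cancel over its 3 time courses, so the second value follows from the first and is no separate measure. The fits with the time course as a block are alternatives. A fixed block takes the spread that a time course shares over its days out of the error. Its tests of a day against day 0 therefore leave out part of the spread between time courses. No pair of arrays had the same values: the highest share of identical Alexa 647 intensities was 0.00667%. Arrays fell into 16 batches by the date in their image names, of 1 to 4 arrays, each within 1 time course and with at least 2 starved days where it held more than 1 array. No count of changed clones could be made within a batch, and scan date was fitted as a term instead. On 1 array of day 3 in time course 1 the file header names the dyes the other way round from the labels. The label's direction, which is also that of the value table, was kept, and fits without that array and with its sign turned were made. Arrays of 1 orientation correlated between -0.12 and 0.96 across days and time courses.

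The rule for named genes, fixed before the data were examined, took the 8 largest rises and 8 largest falls at each day among those past the threshold with the same sign in all 3 time courses, members of gene lists, and a set of single genes. The files pair no clone with a gene, and 0 of the clone identifiers and names were found in the reference table of human genes. The gene lists and single genes were therefore not tested, and the identifiers given are those of the 2 largest rises and 2 largest falls at day 7, a limit set after first counts had been seen. Alternatives fixed before the data were examined covered the normalization, the detection rule, the dye orientations, the arrays, the time courses, the block, the variance model and the value table. Further alternatives were chosen after seeing the data. Models on 48 arrays with missing values use limma's approximate standard errors for differences between days.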

Results

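ARPE-19 cells, an established line of human retinal pigment epithelium, were compared before and after serum was removed from the culture medium. Day 0 cultures were confluent in medium with 10% fetal bovine serum, and starved cultures were kept without serum for 1, 3, 5 or 7 days. RNA was measured on 48 spotted cDNA arrays with 2 channels, 1 for day 0 and 1 for a starved day. No array held a serum-fed culture of a later day, so starvation and time in culture cannot be told apart. Each starved day was measured in 3 time courses, with 4 arrays per day and time course and the dyes exchanged on 2 of the 4. The 4 arrays were averaged to 1 log2 ratio of starved over day 0, so that n = 3 time courses per day. The labels do not state whether the time courses came from separate cultures, so the p-values measure the spread between time courses, which may be technical. The precision is limited by the 3 time courses per day. The files do not pair the clones with genes, and the clones are given by their identifiers. A value in all 12 combinations of day and time course was present for 1387 of the 13167 clones, and these 1387 were tested.

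The question at each starved day was which transcripts had changed from the serum-fed state. Over the 4 days 27 of the 1387 clones passed the test at 1 day or more. Clone hcs071g08 had a log2 ratio of -1.84 at day 3 (SD 0.55, n = 3, limma adjusted p = 0.000304), -1.99 at day 5 (SD 0.29, adjusted p = 0.000108) and -2.33 at day 7 (SD 0.45, adjusted p = 1.19e-05), a 5.03-fold lower level at day 7 with the same sign in 3 of 3 time courses at each day. Its log2 ratio at day 1 was -0.93 (SD 0.44, adjusted p = 0.0582), which passed with the time course as a fixed block (adjusted p = 0.00419) and without time course 1 (-1.15, adjusted p = 0.0374). For a day against day 0 the fixed block leaves part of the spread between time courses out of the error. The day 1 value did not pass without time course 2 (-0.93, adjusted p = 0.740), without time course 3 (-0.71, adjusted p = 0.151) or with a random block (adjusted p = 0.112), and failed in 17 of 27 alternatives, in a range of 2.48e-06 to 0.844. Clone hcs101g12 had log2 ratios of -0.17 and -0.95 at days 1 and 3, which did not pass (adjusted p = 0.790 and 0.455), and of -1.23 at day 5 (SD 0.36, adjusted p = 0.0125) and -1.54 at day 7 (SD 0.59, adjusted p = 0.00140). Without time course 2 its day 5 value was -1.02 and did not pass (adjusted p = 0.318, in a range of 3.30e-13 to 0.489 over all alternatives). Clone hcs001a11 had a log2 ratio of 0.02 at day 1 and 0.42 at day 3 (adjusted p = 0.977 and 0.983), and of 1.21 at day 5 (SD 0.14, adjusted p = 0.000669) and 1.36 at day 7 (SD 0.11, adjusted p = 0.000143). On the arrays with the starved RNA in Alexa 647 alone it did not pass at day 5 (0.49, adjusted p = 0.973) or day 7 (0.94, adjusted p = 0.472, in a range of 1.56e-07 to 0.472 over all alternatives). Clone hcs041a04 rose by 1.69 at day 7 (SD 1.5, adjusted p = 0.0379), with log2 ratios of 3.42, 0.86 and 0.79 in time courses 1, 2 and 3, and its mean did not pass without time course 1 (0.82, adjusted p = 0.114) or without time course 2 (2.10, adjusted p = 0.109). With the time course as a random block it did not pass (adjusted p = 0.0557), and with a fixed block it did. It passed at day 7 under 16 of the 26 alternatives that tested it and did not return the reported values exactly, with adjusted p between 6.57e-06 and 0.345. All 4 clones were detected in the starved channel on at least 10 and in the day 0 channel on at least 11 of the 12 arrays of each day.

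**Figure D1:**
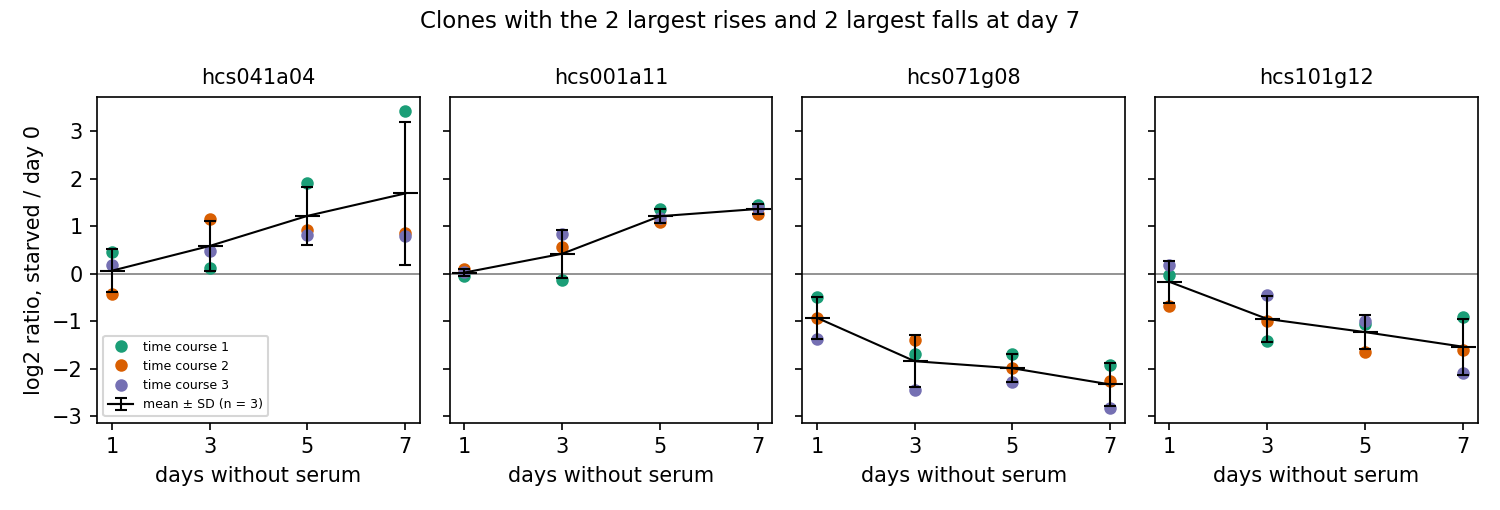
Log2 ratio of starved over day 0 (vertical axis) against days without serum (horizontal axis) for the clones with the 2 largest rises and the 2 largest falls at day 7; dots are time courses, and the line and bars are the mean ± SD (n = 3). At day 7 hcs001a11 lay between 1.25 and 1.45 in the 3 time courses and hcs071g08 between -2.82 and -1.92, while hcs041a04 was at 3.42, 0.86 and 0.79.

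At day 1, 4 of 1387 clones differed from day 0 at an adjusted p below 0.05, and all 4 were lower, 3 of them at least 2-fold, with log2 ratios of -0.91 to -1.27. The same sign was found in all 3 time courses for each. Without adjustment 143 clones had p below 0.05, 138 of them lower, where 69.35 would be expected by chance, as in any comparison of the 1387 clones. The count was 16 without time course 1, 1 without time course 2 and 0 without time course 3 (169 by limma at an unadjusted p below 0.05), and 17 with the time course as a fixed block, 2 higher and 15 lower. The median log2 ratio of all 1387 tested clones was -0.14 at day 1, -0.02 at day 3, 0.09 at day 5 and 0.06 at day 7, between -0.33 and 0.26 in single time courses, and the counts and log2 ratios given here include this shift. After each value was centred on the median of the tested clones, 3, 2, 8 and 12 clones passed at days 1, 3, 5 and 7.

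At day 3 the clone that passed was hcs071g08, and 62 clones had an unadjusted p below 0.05, where 69.35 would be expected by chance. Leaving out time course 1 gave 3 clones, and the fixed block gave 2.

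At day 5, 9 clones passed, 7 of them higher with log2 ratios of 0.79 to 1.21 and 2 lower with -1.23 and -1.99, and 6 of the 9 changed at least 2-fold. Without adjustment 146 clones had p below 0.05, 126 higher and 20 lower. With the time course as a fixed block 23 clones passed, 21 higher and 2 lower, and with median centring in place of loess 45 passed, 42 higher and 3 lower.

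At day 7, 17 clones passed, 6 higher with log2 ratios of 0.60 to 1.69 and 11 lower with -0.68 to -2.33, with the same sign in all 3 time courses for each. At least 2-fold changes were found for 2 of the higher and 7 of the lower clones. Without adjustment 133 clones had p below 0.05. The count was 8 without time course 1 and 5 without time course 2, and 27 with the fixed block, 13 higher and 14 lower. With median centring in place of loess 29 passed, 19 higher and 10 lower.

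The day means were then compared with each other to ask whether the change from day 0 differed between the starved days. Between day 1 and day 7, 31 clones differed, and 24 of them were higher and 7 lower at day 7. The 24 had median log2 ratios of -0.60 at day 1 and 0.57 at day 7, and the 7 had -0.06 and -1.33. For hcs001a11 the difference was 1.34 (adjusted p = 0.00865), and for hcs071g08 and hcs101g12 it was -1.40 and -1.36 (adjusted p = 0.0240 and 0.0335). The median difference over all tested clones was 0.21, and after the centring 18 clones differed, 7 higher and 11 lower. With loess fitted to the tested clones only, 29 differed, 18 higher and 11 lower. Print-tip loess gave 9 clones, 6 higher and 3 lower, and median centring in place of loess gave 47, 41 higher and 6 lower. No clone passed by limma without time course 2 (88 at an unadjusted p below 0.05), 5 passed without time course 3, 17 passed with the time course as a random block, whose estimated correlation was -0.08, and 29 with a fixed block.

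No clone differed by the limma test between days 1 and 3, days 3 and 5 or days 5 and 7. In these comparisons 75, 27 and 26 clones had an unadjusted p below 0.05, where 69.35 would be expected by chance in each. With the 48 arrays as separate values 13 clones differed between days 1 and 3. The F test over the 4 days called 5 clones (adjusted p of 0.0216 to 0.0345), hcs001a11 among them, and all 5 were also called between day 1 and day 7 and were higher at day 7. The F test called 13 clones without time course 1 and 16 with the fixed block. Without time course 2 or 3 it called none by limma. There 64 and 119 clones had an unadjusted p below 0.05, where 69.35 would be expected by chance.

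How far the time courses shared their changes was measured by the correlation of log2 ratios across the 1387 clones, which are not independent replicates. The mean over the 3 pairs of time courses was 0.24 at day 1, 0.11 at day 3, 0.35 at day 5 and 0.39 at day 7. At day 3 time courses 1 and 2 correlated at -0.08. Different days were compared only between different time courses, so that no time course entered a comparison with itself. The number of day 0 RNAs is not stated, and where time courses shared 1, their ratios would correlate without a common response. A dye effect that is unequal between orientations does not cancel and could also raise or lower the correlations. These correlations, within and between days, therefore have no known value for no change. Day 5 and day 7 correlated at 0.34 in the mean (0.15 to 0.51, above 0 in 6 of 6 pairs), day 3 with day 5 at 0.20 and day 3 with day 7 at 0.17. Day 1 correlated with day 5 at -0.08 and with day 7 at -0.07, within a range over pairs of -0.26 to 0.06 and of -0.15 to 0.04. These directions turned in single orientations, where a dye effect does not cancel, to 0.19 and 0.20 with the starved RNA in Alexa 647 and to 0.29 and 0.21 in Alexa 555. They were 0.03 and 0.03 with the first array of each orientation, and day 1 with day 7 was at 0.01 with only manually excluded spots left out.

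**Figure D2:**
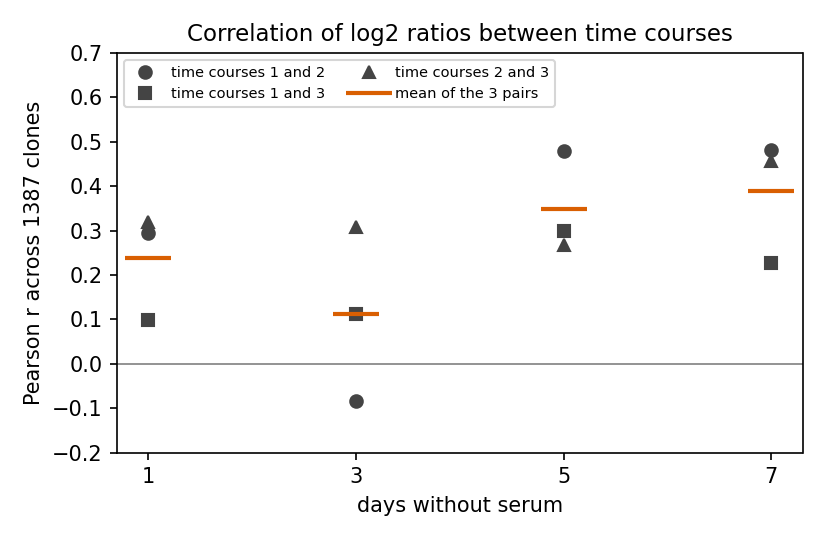
Pearson correlation of the log2 ratios across 1387 clones (vertical axis) for each pair of time courses at each starved day (horizontal axis); the orange dash at each day is the mean of the 3 pairs. The mean was 0.24 at day 1, 0.11 at day 3, 0.35 at day 5 and 0.39 at day 7.

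Arrays of the same day, time course and dye orientation correlated at a median of 0.77 (0.12 to 0.92, 24 pairs). Between opposite orientations, after the ratios were turned to starved over day 0, the median was -0.67 in time course 1 (-0.82 to -0.50, 16 pairs), -0.01 in time course 2 and 0.68 in time course 3. The spread of the ratios over clones was divided into a part that follows the starved RNA and a part that follows the dye. Both parts hold array noise. The starved part is the difference of the orientations divided by 2, so it also holds any dye effect that is unequal between the orientations. In time course 1 the dye part had an SD of 0.48 to 0.52 and the starved part 0.30 to 0.35. In time course 3 the dye part was 0.10 to 0.17 and the starved part 0.26 to 0.35.

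**Figure D3:**
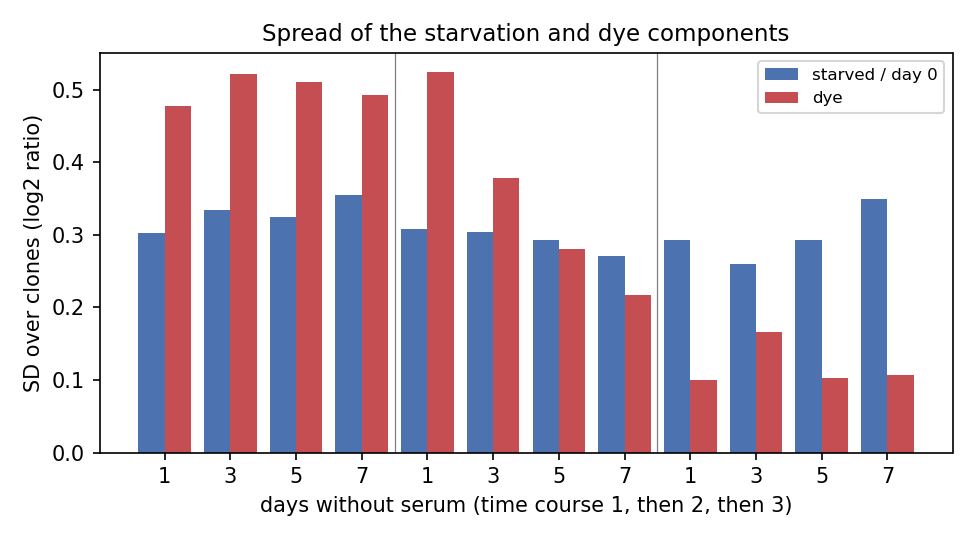
SD over 1387 clones (vertical axis, log2 ratio) of the part of the ratio that follows the starved RNA (blue) and the part that follows the dye (red), for each starved day in time courses 1, 2 and 3. The dye part exceeds the starved part in time course 1 (0.48 to 0.52 against 0.30 to 0.35) and lies below it in time course 3. The starved part also holds array noise and any dye effect that is unequal between the orientations.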

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

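The tests by splits of the values were chosen only after the counts were seen, as were the tests of exclusion marks, dye profile, turned array and centring as alternatives, and the test of the common shift was chosen after the medians of the tested clones and the 24 higher and 7 lower clones had been seen.

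The difference between day 1 and day 7, with 31 clones, and the F test over the 4 days, with 5 clones, stand out. In both, clones passed a limma test of the difference between days itself. Among the 10 splits of the 6 values of days 1 and 7, 1 gave 31 clones or more, the real one, and the highest other count was 0; with 10 splits no share below 0.05 can be reached. For the F test, 6 of 100 splits of the 12 values gave 5 clones or more, the real one included and the others random. The highest count was 204, so chance is not excluded. These splits do not keep the time courses apart, and a count of 204 points to a structure of the values other than the days. With the time course as a fixed block the F test called 16 clones, and 3 of 100 splits that keep 1 value of each time course in each group gave as many, the real one included, with 21 as the highest other count, a share below 0.05. The fixed block was named beforehand and these splits were not. With a random block, whose estimated correlation was -0.08, the F test called 4 clones. No splits were run for that fit, so this count says nothing about chance. The splits without a block and those with the fixed block gave different answers, and they differ in the fit and in which values were exchanged. Whether chance can be excluded is therefore not settled.

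For the 31 clones, a shift of the tested clones as a whole may explain part of the pattern. After each value was centred on the median of the tested clones, 45.2% of the 31 were still called: 7 of the 24 higher clones and 7 of the 7 lower ones. The median difference of the 24 went from 1.30 to 1.11 (SD 0.32 over clones before and after), and their median SE went from 0.272 to 0.255. The median difference thus became smaller while the median SE did not grow. These medians cover all 24, and the adjusted threshold depends on all tested clones, so why single calls ended was not tested. A leftover of the average dye profile is argued against: 93.5% of the 31 were still called after it was removed from each array. Their median size was 1.28 before and after. A dye effect with another profile was not tested, and the dye parts of different time courses of 1 day correlated at only 0.401 in the mean. A change in the cells between day 1 and day 7 stays open beside the common shift and such a dye effect.

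In time courses 1 and 2 arrays of opposite dye orientation of the same day disagreed, with median correlations of -0.67 and -0.01. A clone-specific dye effect goes with the dye parts of different time courses of 1 day, which correlated at 0.401 in the mean (SE 0.0565 over 12 pairs). The 12 pairs share 3 time courses and are not independent, so the SE may be too small. The correlation was 0.58 to 0.68 between time courses 1 and 2, and 0.11 to 0.49 in pairs with time course 3. Wrong labels on all arrays of 1 orientation in time course 1 would move the starvation response into its dye part, while wrong labels on both orientations would leave the disagreement as it is. The former is argued against for time course 1: the mean absolute correlation of its dye part with the starved part of time course 3 was 0.0516, and that of its starved part was 0.18 (SE 0.048, above 0 at 4 of 4 days), although correlations between time courses are low throughout. No biological explanation was tested, as the dyes were exchanged within each day.

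The mean correlation between time courses was 0.24, 0.11, 0.35 and 0.39 at days 1, 3, 5 and 7, with no known value for no change. Removing the dye profile raised the mean correlation over the 4 days by 0.0195 (SE 0.0439), which lies below the 0.05 named beforehand by less than its SE, so a dye effect that differs between arrays, and so does not cancel, stays open; days 1 and 5 fell and day 3 rose by 0.14. The direction of the day 3 array whose header and labels differ is argued against as the cause, since turning it changed the day 3 correlation by -0.0188. The authors' exclusion marks are argued against for these clones only, since using only the manual marks changed their mean correlation by -8.33e-05. They were chosen for complete values under all marks, so this cannot decide about the clones that the marks removed. Over 10688 clones with only the manual marks the mean correlation was -0.0041, -0.12, 0.18 and 0.12 at days 1, 3, 5 and 7. A difference between the time courses in the cells was not tested, as the labels do not state whether they were separate cultures, and stays open.

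For each day against day 0, turning the sign of 1 time course gives 4 sets, and in 1 of the 4 sets, the real one, the count was as high at day 1 (4, highest other 0), at day 3 (1, highest other 0), at day 5 (9, highest other 0) and at day 7 (17, highest other 0); 4 sets are too few for a share below 0.05. For the differences between days 1 and 3, 3 and 5 and 5 and 7, where the real count was 0, all 10 of 10 splits gave as many, and the highest other counts were 230, 0 and 0. The split with 230 clones put days 1 and 3 of time course 1 with day 1 of time course 2, which points to a structure of the values other than the days; the medians of all tested clones were -0.11, -0.33 and -0.29 in these and -0.02 to 0.26 in the other values.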

How the results depend on the processing

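The alternatives for exclusion marks, values in 2 time courses, normexp, dye profile, header, scan date, centring on the tested clones, loess on the tested clones, all clones on the array and weights were chosen after seeing the data, 12 of the 31 settings. Gene lists and single genes were not run, as no clone is paired with a gene, and plain background subtraction was not run, as no background columns are given. No background correction, both other detection rules and Aquantile scaling returned the reported values exactly, so these 4 say nothing about stability and are left out of the tallies below.

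In 1564 pairs of a clone called in the reported tests and 1 of the other 27 settings, 0 changed sign; these clones were called for a large change, which makes a turn of sign less probable. The counts moved. Counts below are for days 1, 3, 5 and 7, the F test, and day 7 minus day 1, each only where it left the range within 1.5 times the reported 4, 1, 9, 17, 5 and 31; the cause was not tested unless given. Median centring gave 45 at day 5, 29 at day 7, 23 by the F test and 47 for day 7 minus day 1. Print-tip loess gave 17 at day 5, 2 by the F test and 9 for day 7 minus day 1. The first array of each orientation, which left 233 clones, gave 1 at day 5, 6 at day 7 and 8 for day 7 minus day 1, and the second array, with 559 clones, gave 8, 4, 4, 9 and 11 for day 1, day 5, day 7, the F test and day 7 minus day 1. Arrays with starved RNA in Alexa 647 alone (1981 clones) gave 13, 4, 3, 8, 0 and 0, and those in Alexa 555 alone (2380 clones) gave 0, 5, 56, 11, 0 and 0; there the dye effect does not cancel. At an unadjusted p below 0.05, 58 and 124 clones (Alexa 647) and 49 and 89 clones (Alexa 555) stood beside the limma counts of 0 by the F test and for day 7 minus day 1, and 214 beside that at day 1. Chance alone would give a share of 0.05 of the clones tested. The counts of 124 and 214 lie above that share, and 58, 49 and 89 lie below it.

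Without 1 time course the counts were 0 to 16 at day 1, 1 to 3 at day 3, 6 to 9 at day 5, 5 to 13 at day 7, 0 to 13 by the F test and 0 to 22 for day 7 minus day 1. Each day fitted alone gave 56, 2 and 99 at days 1, 3 and 5. A random block for the time course, with an estimated correlation of -0.08, gave 17 for day 7 minus day 1, and a fixed block 17, 2, 23, 27 and 16 for days 1, 3, 5, 7 and the F test. For the days against day 0 the fixed block leaves part of the spread between time courses out of the error. With 48 arrays, a random block and a dye term the counts were 52, 7, 64, 63, 53 and 57, and 13 between days 1 and 3; this takes arrays, not time courses, as the units. With scan date as a term they were 38, 16, 45, 50 and 33, and 5 between days 1 and 3, and with a dye term for each scan date 65, 2, 32, 49, 52 and 65, and 11 between days 1 and 3.

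Leaving out only manually excluded spots (10688 clones) gave 0, 3, 30, 0 and 0 for day 1, day 3, day 7, the F test and day 7 minus day 1. Beside the limma counts of 0, 465, 417 and 722 clones had an unadjusted p below 0.05. Chance alone would give a share of 0.05 of the 10688 clones. The counts of 465 and 417 lie below that share, and 722 lies above it. Values in 2 time courses (3866 clones) gave 2, 29, 40 and 11 at day 3, day 5, day 7 and for day 7 minus day 1. Normexp gave 13 at day 1. Removal of the dye profile gave 17 at day 1, 37 at day 7 and 24 by the F test. The array whose header differs gave 7 at day 1 when left out and 13 when turned. Centring on the tested clones gave 2 at day 3 and 18 for day 7 minus day 1, and loess on the tested clones gave 15 at day 5, 40 at day 7 and 0 by the limma F test (141 unadjusted). All clones on the array, 1429 with complete values, gave 5, 1, 10, 18, 5 and 32. Weights for each day and time course, whose estimation stopped before convergence and gave day 3 of time course 3 a weight of 37.9 against at most 2.66 elsewhere, gave 16, 692, 71, 120, 287 and 80, with 125 between days 1 and 3 and 118 between days 3 and 5, and are not read as results.

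No clone differed between days 5 and 7 by limma in any of the 26 such settings that tested it. In the reported test 26 clones had an unadjusted p below 0.05, where 69.35 would be expected by chance. Values of named clones changed sign only at days 1 and 3, where none of these values passed. Clone hcs001a11 at day 1 went to -0.018 (median centring), -0.045 (print-tip loess), -0.11 (second array), -0.39 (Alexa 647), -0.061 (manual exclusion) and -0.00083 (weights), and at day 3 to -0.28 (Alexa 647). Clone hcs041a04 at day 1 went to -0.0057 (second array) and -0.62 (Alexa 647), and at day 3 to -0.21 (Alexa 647). Without 1 time course the day 1 values ran from -0.0099 to 0.063 for hcs001a11, from -0.13 to 0.31 for hcs041a04 and from -0.35 to 0.080 for hcs101g12. At day 7 hcs071g08 passed in 27 of 27 settings that tested it, hcs101g12 in 26 of 26, hcs001a11 in 25 of 26 and hcs041a04 in 16 of 26. Over 17 settings the mean correlation between time courses lay between -0.0041 and 0.30 at day 1 and between -0.12 and 0.36 at day 3. It lay between 0.18 and 0.46 at day 5 and between 0.12 and 0.45 at day 7. That of different days lay between -0.13 and 0.29 for day 1 with day 5 and between -0.09 and 0.21 for day 1 with day 7. Signal over background cannot be given, as the files hold no background; the share of spots detected was 27.3 to 92.7% in Alexa 555 and 36.5 to 95.1% in Alexa 647 over arrays.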

Other observations

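The prefixes were examined after the data were seen, as they are not among the groups chosen beforehand. The clones carry name prefixes whose meaning the files do not state, and the prefixes differed in how many of their clones could be tested. Of the 809 clones with the prefix he, 358 (44.3%) had complete values, and of the 336 tested among 958 with the prefix hd the share was 35.1%. Of the 5038 clones with the prefix cs, 108 (2.14%) had complete values, and of the 1030 with the prefix fg, 9 did (0.874%). The tested clones are therefore not an even sample of the array.

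The hypothesis that clones sharing a prefix shift together was tested with camera over the prefixes with at least 20 tested clones and the 4 days. The smallest adjusted p was 4.82e-05 with the preset correlation of 0.01, and 8 pairs of prefix and day passed. The 108 cs clones had a mean log2 ratio of -0.31 at day 1 against -0.15 for the other clones (adjusted p = 0.000996), and of 0.27 at day 5 against 0.09 (adjusted p = 4.82e-05). The 118 bx clones had 0.12 against -0.02 at day 3 (adjusted p = 4.82e-05) and 0.25 against 0.09 at day 5 (adjusted p = 0.00381). At day 5 the by clones were also higher than the others (0.23 against 0.10, adjusted p = 0.0435), and 3 prefixes were lower: he (0.05 against 0.13, adjusted p = 0.0435), ho (0.02 against 0.12, adjusted p = 0.0201) and hq (-0.0056 against 0.11, adjusted p = 0.0435). With an estimated correlation no pair passed, with adjusted p = 0.990 for each of these 8. Clones of one prefix may therefore vary together between arrays without a response to starvation. The prefixes that were higher at day 5 had mean log2 intensities of 11.8 (bx), 11.3 (by) and 11.1 (cs). Those that were lower had 10.9 (he), 10.8 (ho) and 10.9 (hq). Intensity did not go with the day 5 shift in every prefix. With the preset correlation, hw had 11.1, as cs did, but 0.12 against 0.11 (adjusted p = 0.391). The hd clones had 10.8, as ho did, but 0.09 against 0.11 (adjusted p = 0.826). The fs (11.2) and hp (10.99) clones leaned with intensity without passing (0.19 against 0.10 and 0.04 against 0.11, adjusted p = 0.208 for each). Prefixes were not compared among clones of equal intensity, so how far intensity accounts for the shifts was not tested.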
